A study of Mus musculus with 4 samples.

How the data were processed

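The series measured RNA in cultures of mouse osteoclasts, the multinucleated cells that resorb bone and that form from macrophages when the cytokines M-CSF and RANKL act on them. Per the labels' protocols, bone marrow from wild-type C57BL/6J mice was grown for 3 days with conditioned medium of L929 cells, a fibroblast line that secretes M-CSF, at the equivalent of 20 ng/ml of recombinant M-CSF. The attached macrophages were reseeded and given 40 ng/ml RANKL with either the solvent DMSO or 10 µM BMS-582949, a small-molecule inhibitor of the kinase p38α, and RNA was taken at day 4. The sources differ on how long the compound was present: the design text gives 3 days before a change of medium, and the treatment protocol gives 4 days. That protocol is worded alike for all 4 samples and names the compound also for those labelled DMSO, so the groups were taken from the treatment label. The titles of the treated samples write the compound with transposed digits, and the spelling of the treatment label is used. Each group has 2 libraries, prepared from TRIzol-extracted RNA with an mRNA kit of the Hieff NGS Ultima series, per the labels.

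The deposited table holds raw counts per gene, as the whole-number values of unequal column sums show. Per the submitters' processing notes, the authors used Trimmomatic 0.36, HISAT2 2.0.4 and DESeq2 1.30.1 with the mouse build GRCm38. The notes as used here give no roles or order for these tools. The counting tool, the gene annotation and whether strand was used in counting are not given in the sources used here. The table lists 23390 gene models, of which 22036 carry Ensembl identifiers and 1354 are models that the authors named NewGene and for which no coordinates were used here. Symbols, coordinates and gene types for 22022 of the Ensembl identifiers came from GENCODE M21, which is on GRCm38. Nearly all of these (21914) are protein-coding. No count was recorded in any library for 6687 models. Every column was assigned to its sample by name.

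Depth was 35331889 and 36178333 counts in the DMSO libraries and 39255925 and 37455168 in the BMS-582949 libraries. At this depth, counting error is small for well-expressed genes, and intervals given for a share of counts are exact Clopper-Pearson 95% intervals that cover counting error only, since the reads carry no molecular identifiers that were used here. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Their counts differ beyond sampling noise (chi-square per degree of freedom 9.83 for DMSO and 13.9 for BMS-582949), so they were counted as 2 samples each.

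Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr at its default minimum count of 10, which left 13214 genes. Libraries were scaled with TMM, dispersions were estimated, and a quasi-likelihood F test (glmQLFit, glmQLFTest) compared BMS-582949 with DMSO without covariates, leaving 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-scaled and given as mean ± SD of 2 libraries, and log2 fold changes are BMS-582949 minus DMSO. Before the data were examined, 28 gene lists were fixed. The 26 lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26. Camera was repeated with an estimated correlation, and fry was run to test whether a list moves one way as a whole. Both the estimate of correlation and the p-value that camera gives with it rest on 2 residual degrees of freedom.

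Genes are named by a rule also fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 10, separate groups and a gene name. It adds up to 2 called members per direction of each list with a mean CPM of at least 1, and 14 genes whatever their result. A gene that only its list brings in may be left out where the list is not described gene by gene. Genes named outside this rule are said to be so. The values of 2 genes that the rule takes are not reported here.

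Alternatives fixed in advance were DESeq2 size factors, upper-quartile scaling, library size only, no low-count filter, a minimum of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, leaving out the mitochondrially encoded genes, a replicate block and leaving out each library. For counts of genes they also included an adjusted p under 0.01, a minimum absolute log2 fold change of 1 and glmTreat against 1.5-fold. Filtering was redone in each fit, so the tested members of a list could differ between fits. Added after seeing the data were a crossed replicate block, removal of each library's trend on GC content and exon length (loess, span 0.3), and runs without the NewGene models and without models whose exons overlap another model by at least 10%. For the named genes and list members, the percentage of transcript words of 50 bases that also occur in another gene was computed from GENCODE M21 transcripts, since reads from such stretches may be split between genes.

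The fit was tested on simulated counts with the real means, library sizes and dispersions, in which 200 genes were changed. As many were raised as lowered, and they were drawn only from genes above a minimum mean CPM. Recovery of genes with fewer counts, and scaling when many genes change, were thus not tested. Of 12999 genes run, it recovered 62.0% of the 50 genes changed 1.5-fold, 98.0% of those changed 2-fold, and all those changed 4-fold or 8-fold. It also called 14 of 12799 unchanged genes, which is 7.22% of its calls.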

Results

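RNA was sequenced from mouse bone marrow-derived macrophages driven towards osteoclasts with 40 ng/ml RANKL and M-CSF, with DMSO (2 libraries) or with 10 µM of the p38α inhibitor BMS-582949 (2 libraries). The comparison asks what the inhibitor does to gene expression while osteoclasts form. Total counts were 35331889 and 36178333 in the DMSO libraries and 39255925 and 37455168 in the BMS-582949 libraries. Across genes, log2 CPM correlated at a Pearson r of 0.986 between the DMSO libraries and 0.985 between the BMS-582949 libraries, and at 0.932 to 0.934 between libraries of different groups. Genes are not independent replicates, so these values only describe agreement. The first principal component held 80.8% of the variance and separated the groups.

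With BMS-582949 all 20 tested bone resorption genes were called lower, while all 34 cell cycle genes, 13 of 20 macrophage markers and 25 of 29 interferon-stimulated genes were called higher. As lists these were past camera with the preset correlation, and none was with an estimated correlation (adjusted p = 0.12, 0.11, 0.30 and 0.60). Camera with the estimate takes its p-values from the 2 residual degrees of freedom. Of 13214 genes tested, 4035 were called higher and 3919 lower with BMS-582949 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1314 of the former and 1499 of the latter changed at least 2-fold. Both libraries of one group lay above both of the other for 80.2% of tested genes, against 33.3% by chance. The split between directions depends on scaling. With library size only, 6738 genes were called higher and 2240 lower (75.1% against 24.9% of calls, where TMM gave 50.7% and 49.3%), because that scaling moved the median log2 fold change of all genes from 0.03 to 0.41. Changes below are relative to TMM. They describe whole cultures, so a changed share of osteoclasts cannot be told apart from changed expression per cell.

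**Figure D1:**
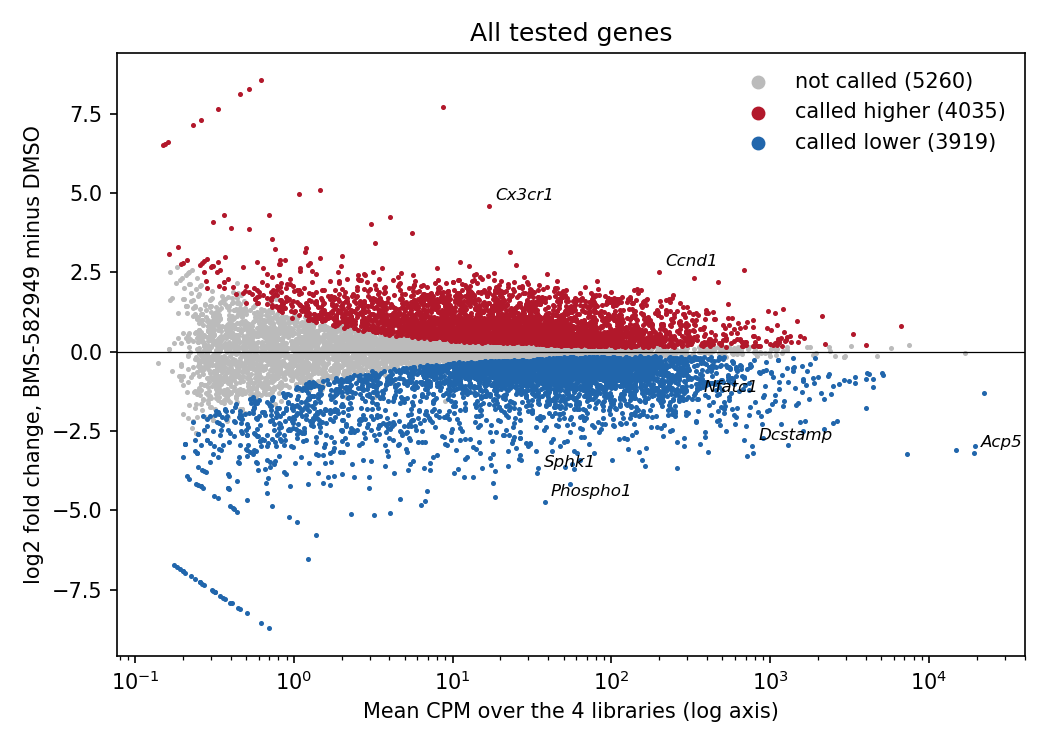
Each point is 1 of 13214 tested genes, with its mean CPM over the 4 libraries on a log axis and its log2 fold change (BMS-582949 minus DMSO). Red marks the 4035 genes called higher and blue the 3919 called lower; diagonal rows of points at low CPM are genes without counts in one group, whose fitted fold change is no estimate of size.

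All 20 tested genes of the bone resorption list fell with BMS-582949 (20 lower when adjusted over the list alone). Acp5, which encodes the tartrate-resistant acid phosphatase used as an osteoclast marker, went from 34765 ± 723 CPM in DMSO to 3765 ± 120 CPM (n = 2 each), a log2 fold change of -3.21 ± 0.10 (SE, adjusted p = 1.2e-10). The collagen-degrading protease gene Ctsk changed by -2.96, the matrix metalloproteinase gene Mmp9 by -3.09, the creatine kinase gene Ckb by -3.23 and the integrin gene Itgb3 by -1.90. The list's median log2 fold change was -2.11 (camera adjusted p = 1.8e-69). With an estimated correlation the adjusted p was 0.12. Acp5, Ctsk, Mmp9 and Ckb together took 9.40% and 9.70% of all counts in the DMSO libraries and 1.45% in each BMS-582949 library. For Acp5 alone the share was 3.01% (95% interval 3.008% to 3.019%) and 3.08% in DMSO against 0.424% (0.422% to 0.426%) and 0.435% with the inhibitor.

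On GRCm38 (GENCODE M21), Acp5 (ENSMUSG00000001348) lies on chromosome 9 at 22126727 to 22135711, Ctsk (ENSMUSG00000028111) on chromosome 3 at 95499256 to 95509362 and Mmp9 (ENSMUSG00000017737) on chromosome 2 at 164940780 to 164955850. Values are sums over each gene model, without a split into exons or transcripts.

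Among the 26 genes of osteoclast differentiation and fusion, 19 fell, 5 rose and 2 were not called, with the same counts when adjusted over the list alone. Dcstamp and Ocstamp, which encode membrane proteins needed for the fusion of precursors, fell by 2.98 and 2.99 on the log2 scale. Oscar, an immunoglobulin-like co-receptor gene, went from 727 ± 11.5 to 81.1 ± 4.11 CPM and Slc9b2, a sodium/proton exchanger gene, from 1403 ± 48.6 to 153 ± 2.02 CPM. Nfatc1, the transcription factor that drives the osteoclast programme, changed by -1.48 ± 0.07 (SE), and Tnfrsf11a, the receptor for RANKL, by -0.55 ± 0.06, from 163 ± 0.846 to 112 ± 0.912 CPM. The members that rose included Adam8 (from 284 ± 15.8 to 804 ± 21.3 CPM), Trem2 (1.17) and Fos (0.82, from 220 ± 5.54 to 389 ± 7.59 CPM), a component of the AP-1 transcription factor. The list's median was -1.03 (camera adjusted p = 6.4e-15), and -0.64 with library size only. Its adjusted p was 0.26 with an estimated correlation.

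Macrophage markers moved the other way as a list, though not as one. Of 20 tested, 13 rose, 2 fell and 5 were not called, and 4 fell when adjusted over the list alone. The chemokine receptor gene Cx3cr1 (chromosome 9, 119901616 to 120069879) rose from 1.34 ± 0.257 to 32.4 ± 1.57 CPM, a log2 fold change of 4.59 ± 0.16 (SE, adjusted p = 2.4e-10), and the mannose receptor gene Mrc1 rose by 1.57. The M-CSF receptor gene Csf1r went from 1977 ± 129 to 883 ± 11.1 CPM (-1.16), and the lysosomal glycoprotein gene Cd68 changed by -1.35. Exons of Csf1r overlap another gene model over 15.1% of their length. The list's median was 0.69 (camera adjusted p = 2.5e-05), and the adjusted p was 0.30 with an estimated correlation. Scaling by library size only gave 16 higher and a median of 1.06.

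Of 16 genes listed as negative regulators of osteoclast formation, 11 rose and 2 fell (12 and 2 adjusted over the list alone). Whether each member restrains osteoclast formation was not tested here. The list's median was 0.92 (camera adjusted p = 3.3e-03, and adjusted p = 0.47 with an estimated correlation). Irf8, a transcription factor of the myeloid lineage, went from 14.9 ± 0.610 to 33.4 ± 0.234 CPM (1.17) and Socs3, a suppressor of cytokine signalling, rose by 1.61. The fallers were Tnfaip3 (-1.17), an inhibitor of NF-kB signalling, and Cyld (-0.42), a deubiquitinase gene whose call ended with library size only.

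**Figure D2:**
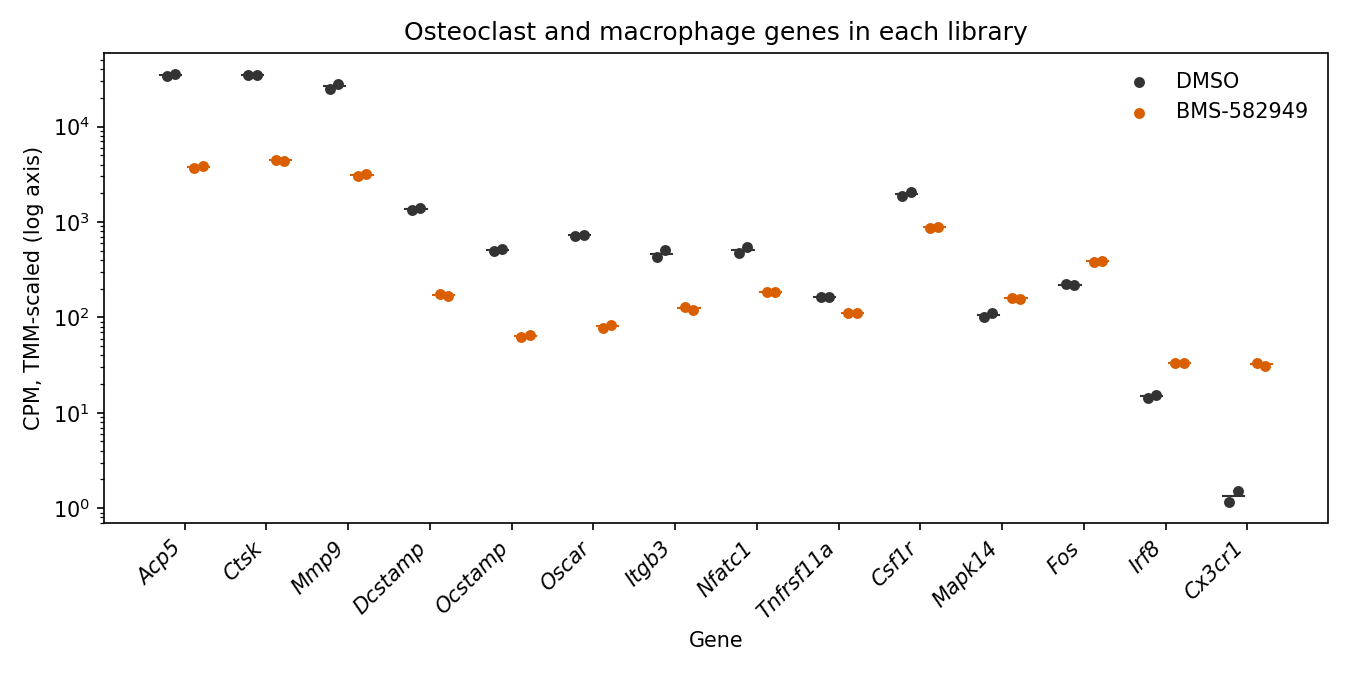
CPM (TMM-scaled, log axis) of 14 genes in each of the 2 DMSO libraries (dark points) and the 2 BMS-582949 libraries (orange points), with short lines at the group means. Genes from Acp5 to Csf1r are lower with BMS-582949 and genes from Mapk14 to Cx3cr1 are higher, in both libraries of each group.

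All 34 cell cycle genes rose (34 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 1.8e-38, and adjusted p = 0.11 with an estimated correlation). Mki67, a marker of proliferating cells, went from 28.6 ± 0.439 to 135 ± 6.00 CPM, and the kinetochore gene Cenpf from 5.56 ± 0.736 to 30.8 ± 1.73 CPM. Ccnd1, which encodes cyclin D1 and was not on that list, rose by 2.50 ± 0.08 (SE). Exons of Ccnd1 overlap another model over 23.4% of their length. Of 29 interferon-stimulated genes tested, 25 rose and 1 fell, with the same counts adjusted over the list alone and a median of 1.38 (camera adjusted p = 9.4e-05, and adjusted p = 0.60 with an estimated correlation), and 23 rose and 2 fell with the GC and length trend removed. Cmpk2 rose by 2.70 and the chemokine gene Cxcl10 by 2.35, both from low levels (0.528 ± 0.209 and 1.49 ± 0.671 CPM in DMSO). Oasl1, of the oligoadenylate synthetase-like family, fell by 1.17.

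All 25 nuclear-encoded genes of oxidative phosphorylation fell (25 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 1.7e-26, and adjusted p = 0.18 with an estimated correlation), and -0.74 with library size only, where all 25 fell too. Sdhb, of respiratory complex II, went from 657 ± 0.664 to 218 ± 1.60 CPM, and Ndufa4 changed by -1.50. The share of counts from the 13 mitochondrially encoded genes was 6.52% and 5.85% in DMSO and 3.60% and 4.07% with BMS-582949. Glycolysis and hypoxia genes fell in 17 of 20 cases (18 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 2.5e-06, and adjusted p = 0.21 with an estimated correlation). These counts were 14 lower and 2 higher with library size only (median -0.35). The prolyl hydroxylase gene Egln3 changed by -3.96 from 3.08 ± 0.642 CPM and Ankrd37 by -2.25 from 2.64 ± 0.683 CPM. Exons of Ankrd37 overlap another model over 26.4% of their length. Both fold changes rest on few counts, 4 and 13 for Egln3 and 39 and 10 for Ankrd37 in the BMS-582949 libraries. Without BMS-582949 replicate 1 the changes were -3.32 and -3.47, and without BMS-582949 replicate 2 they were -5.09 and -1.63.

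Lysosomal genes fell in 15 of 20 cases and rose in 3, with the same counts adjusted over the list alone and a median of -1.31 (camera adjusted p = 4.8e-12, and adjusted p = 0.40 with an estimated correlation). Under library size only 5 rose. Hexa, a lysosomal glycosidase gene, fell by 2.24, while the protease gene Ctsl rose by 1.29 and the membrane protein gene Lamp1 by 1.23. Exons of Hexa overlap another model over 12.8% of their length. The podosome and actin ring list, on adhesion structures of osteoclasts, had 15 lower and 2 higher of 19, also when adjusted over the list alone (median -0.51, camera adjusted p = 9.4e-05, and adjusted p = 0.59 with an estimated correlation). Scaled by library size only, 9 were lower and 4 higher (median -0.13). Rac2, a small GTPase gene of blood cells, changed by -2.28 and the cortactin gene Cttn by -2.11. Cholesterol synthesis genes fell in 14 of 20 cases (16 adjusted over the list alone), with Insig1 at -1.46 (median -0.69, camera adjusted p = 1.6e-03, and adjusted p = 0.48 with an estimated correlation), and with library size only 10 fell and 4 rose (median -0.31). Of 13 genes of the NRF2 and xenobiotic response, 10 rose and 2 fell (11 and 2 adjusted over the list alone), among them Nqo1, a quinone reductase gene, at 1.41 (median 0.52, camera adjusted p = 3.6e-03, and adjusted p = 0.30 with an estimated correlation). With library size only, 11 of them rose and 1 fell (median 0.90), and the median was 0.50 without DMSO replicate 1.

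Factors through which osteoclasts act on bone-forming cells fell in 6 of 10 cases and rose in 2, with the same counts adjusted over the list alone. The sphingosine kinase gene Sphk1 went from 63.9 ± 2.41 to 4.48 ± 0.211 CPM (-3.83) and the cytokine gene Lif from 64.1 ± 7.77 to 5.04 ± 0.409 CPM (-3.67). The complement gene C3 rose by 2.44 and Cxcl16 by 1.41. Exons of Cxcl16 overlap another model over 18.3% of their length. The list's median was -0.91 (camera adjusted p = 0.030, and adjusted p = 0.40 with an estimated correlation), and -0.53 with library size only, where 3 rose. Besides the estimated correlation, its call ended under 6 other settings, with adjusted p from 0.052 to 0.085, among them the fits without DMSO replicate 1 (0.064) and without BMS-582949 replicate 1 (0.052).

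**Figure D3:**
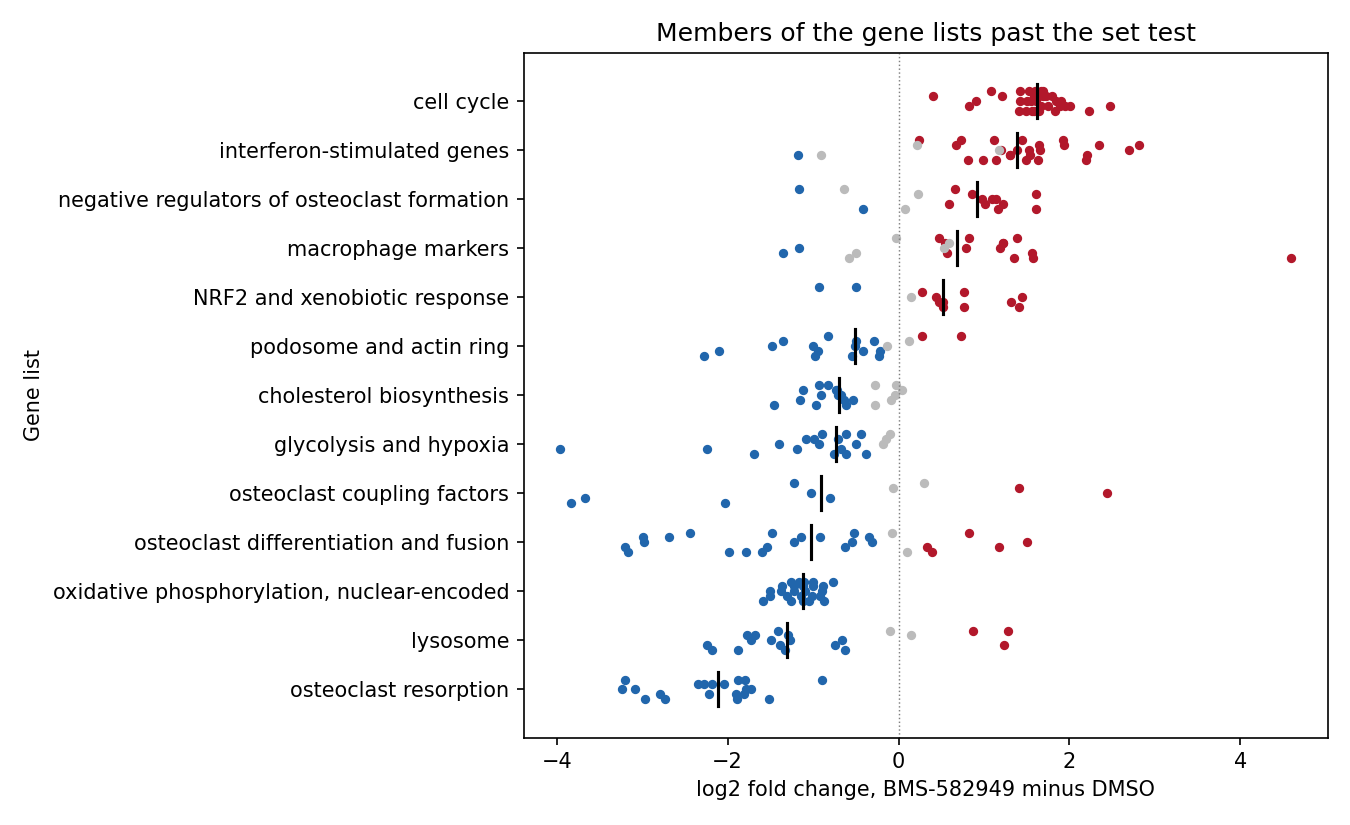
Log2 fold change (BMS-582949 minus DMSO) of each tested member of the 13 gene lists past the camera test with the preset correlation, with red points called higher, blue points called lower, grey points not called and black bars at the list medians. The medians run from -2.11 for osteoclast resorption to 1.63 for the cell cycle list.

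Genes of the p38 pathway itself moved both ways. Of 22 tested, 10 rose and 5 fell, with the same counts adjusted over the list alone (median 0.11, camera adjusted p = 0.44). The counts were 15 and 2 with library size only (median 0.49). The median was 0.28 without BMS-582949 replicate 1 and 0.003 with the GC and length trend removed. Mapk14, which encodes p38α, went from 106 ± 7.73 to 158 ± 2.33 CPM (0.58 ± 0.07 SE), and the transcription factor gene Mef2c and the kinase gene Map3k5 rose by 1.86 and 1.61. Mknk2 fell by 0.89. Immediate early and MAPK feedback genes rose in 9 and fell in 12 of 26 cases, also adjusted over the list alone, with camera and the median (-0.07) differing in sign (adjusted p = 0.83). The balance depends on processing, with 13 rising and 4 falling with library size only (median 0.31) and 9 and 8 with the GC and length trend removed (0.14). Leaving out DMSO replicate 1, BMS-582949 replicate 1 or BMS-582949 replicate 2 gave medians of -0.01, -0.21 and -0.18, with 11, 8 and 12 falling. Myc rose by 1.55 and Spry1, an antagonist of growth factor signalling, fell by 3.03. Of 15 cytokine and chemokine genes tested, 4 rose and 4 fell (3 and 4 adjusted over the list alone). Ccl2 rose by 2.38 and Lif fell as above, and camera (adjusted p = 0.94) and the median of 0.15 differed in sign. The median was 0.30 without DMSO replicate 1, 0.070 without BMS-582949 replicate 1 and -0.14 without BMS-582949 replicate 2. It was 0.53 with library size only and 0.27 with the GC and length trend removed, where 5 rose and 4 fell.

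NF-kB feedback targets rose in 10 and fell in 4 of 15 cases, also adjusted over the list alone (median 0.39, camera adjusted p = 0.34), and fry gave an adjusted p of 0.027. The counts were 12 and 2 with library size only. Remaining pathway lists were not past the camera test, and their counts are the same when adjusted over each list alone. Of 11 MHC class II presentation genes, 5 rose and 1 fell (median 0.38, adjusted p = 0.29). The counts were 7 and 0 with the GC and length trend removed (median 0.55). These were 8 and 0 with library size only (median 0.77), 3 and 0 without DMSO replicate 1, 5 and 0 without DMSO replicate 2, 6 and 0 without BMS-582949 replicate 1 and 3 and 1 without BMS-582949 replicate 2 (median 0.23). Of 6 genes of alternatively activated macrophages, 2 rose and 2 fell (median 0.21, mean -0.13, adjusted p = 0.83), and the median was -0.24 without DMSO replicate 1, -0.14 without DMSO replicate 2, 0.13 without BMS-582949 replicate 2 and 0.59 with library size only. Of 15 LXR and lipid genes, 6 rose and 6 fell (median 0.05, adjusted p = 0.54). That split depends on scaling and on single libraries, with 11 and 1 with library size only (median 0.44), 5 and 3 without DMSO replicate 2 (0.12), 6 and 3 without BMS-582949 replicate 1 and 7 and 6 without BMS-582949 replicate 2 (0.10). Of 16 ATF4 and unfolded protein response genes, 4 rose and 8 fell (median -0.21, adjusted p = 0.90), against 7 and 6 with library size only (median 0.17), and the median was -0.13 without BMS-582949 replicate 1 and -0.32 without BMS-582949 replicate 2.

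Markers of other cell types were mostly low. Among 11 stromal genes, 7 fell and 1 rose (median -0.53, camera adjusted p = 0.30), and without DMSO replicate 2 the list was called lower (median -0.59, adjusted p = 0.031). Under library size only 2 fell and 2 rose (median -0.14), and the rise was not called without DMSO replicate 2 or BMS-582949 replicate 1. Col3a1 went from 38.6 ± 7.16 to 19.6 ± 0.823 CPM. Neutrophil markers had 2 higher and 3 lower of 11 (median -0.66, adjusted p = 0.90), dendritic cell markers 1 lower of 4 (median -0.85, adjusted p = 0.80, with Itgax at -0.92 and fry adjusted p = 0.027), and B cell and erythroid markers no call among 3 and 4 (medians 0.29 and 0.41, adjusted p = 0.90 and 0.83). Only 2 T and NK cell genes (1 higher) and 2 mast cell genes (both lower) had enough counts, too few for a set test. Counts adjusted over each of these lists alone were the same.

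These low markers depend on single libraries, and the tested members changed with them. For dendritic cell markers, 6 genes were tested in each fit named below, against 4 with all libraries. Neutrophil markers had 2 higher and 1 lower without DMSO replicate 2, 1 and 4 without BMS-582949 replicate 2, and medians of -0.40 without DMSO replicate 1 and -0.34 without BMS-582949 replicate 1. Dendritic cell markers had 1 higher and 2 lower without BMS-582949 replicate 1 (median -0.23), and a median of -0.53 without DMSO replicate 2. The B cell median was -0.34 without DMSO replicate 1, 1.06 without DMSO replicate 2, 0.59 without BMS-582949 replicate 1 and 0.15 without BMS-582949 replicate 2. The erythroid median was 0.13 without DMSO replicate 1 and 1.13 without DMSO replicate 2. The T and NK cell call ended without BMS-582949 replicate 1. The mast cell list had 1 gene called lower without DMSO replicate 1 and 0 without DMSO replicate 2 or BMS-582949 replicate 2.

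Of the 26 lists, 13 were past camera with the preset correlation (5 higher and 8 lower), none with an estimated correlation, where 4 had an unadjusted p under 0.05, and 15 with fry.

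The largest rises among called genes with a mean of at least 10 CPM, after Cx3cr1, were the medium-chain fatty acid receptor gene Gpr84 (3.13), the argininosuccinate synthase gene Ass1 (2.73), the adhesion molecule gene L1cam (2.69), Ly6e (2.58, from 196 ± 7.86 to 1173 ± 167 CPM), Ccnd1, Cenpf and the cytokine gene Il16 (2.46). The largest falls were the phosphatase gene Phospho1 (-4.76), the histone genes Hist2h3c2 (-4.59) and Hist2h2aa2 (-4.17), Klra17 (-4.14), Mustn1 (-3.95), Enpp5 (-3.94), Sphk1 (-3.83) and Esyt3 (-3.83). Phospho1, Hist2h3c2, Hist2h2aa2 and Ass1 share 85.4%, 63.5%, all and 38.6% of their 50-base words with other genes, respectively, so their values are uncertain, and Phospho1 exons overlap another model over 89.6% of their length. Gpr84 shares 37.8% of its words with transcripts of the opposite strand, and Il16 exons overlap another model over 15.3%. The BMS-582949 libraries held 115 and 382 counts of Hist2h2aa2, which changed by -3.52 without the first and by -5.37 without the second.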

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

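With library size only, 6738 genes were called higher and 2240 lower, and this scaling shifted log2 fold changes by a median of 0.38 against TMM. A minimum absolute log2 fold change of 1 left 1314 and 1499 genes, and glmTreat against 1.5-fold 1572 and 1824; both ask for larger changes by construction. All other settings gave counts within 1.5 times those reported. Leaving out 1 library, with the lone library assumed to vary like the other group, gave 3615 to 3711 genes called higher and 3509 to 3903 lower. The median log2 fold change then ranged from -2.20 to -2.04 for the resorption list, from -1.09 to -1.003 for the differentiation and fusion list and from 0.59 to 0.84 for macrophage markers, all past camera. With an estimated correlation these 3 lists kept their medians of -2.11, -1.03 and 0.69. They lost their calls (adjusted p = 0.12, 0.26 and 0.30), as did the other 10 called lists. For the cell cycle, glycolysis and hypoxia and NRF2 lists the estimates were -0.0036, -0.046 and -0.057, below the preset 0.01. The list of factors acting on bone-forming cells had -0.073. These values argue against a higher correlation between genes as the cause for those lists. Camera with an estimated correlation also takes its p-value from the 2 residual degrees of freedom, unlike camera with the preset. For the cell cycle list the unadjusted camera p was 1.4e-39 with the preset and 4.3e-03 with the estimate. For lists with estimates above the preset, the few degrees of freedom and the higher correlation were not separated as sources of the loss.

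Equal replicate numbers are not stated to pair libraries, and the deviations of equally numbered libraries correlated at a Pearson r of -0.30 across 8486 genes. The replicate block called 3923 genes higher and 3830 lower, with medians of the 3 lists under the replicate block within 1.5 times those above. The crossed replicate block, added after seeing the data, called 4163 and 4038.

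Several lists outside the camera threshold changed direction by camera, and the cause was not tested. Camera compares a list with all other genes, so its direction can change while the list's median keeps its sign. With library size only, the lists that changed were the ATF4 list (median 0.17), B cell markers (0.66) and erythroid markers (0.79). Their medians with TMM were -0.21, 0.29 and 0.41. With a minimum of 1 CPM, neutrophil markers did so (-0.21), and with limma-voom immediate early genes (-0.070) and cytokines (0.27). Cytokines also did so with the replicate block (0.25) and in 3 of the 4 fits that left out a library (medians 0.070 to 0.30), but not without BMS-582949 replicate 2 (-0.14). So did B cell markers without DMSO replicate 1 (-0.34, in a range up to 1.06). With the GC and length trend removed, a choice made after seeing the data, so did the ATF4 list (-0.14) and neutrophil markers (-0.45). H2-DMb1 reversed with library size only (0.082). Depth limits genes under about 1 CPM, where several cytokine and other-cell markers lie.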

Other observations

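The gene families below were chosen after the data were seen, so they are described by counts and medians, without a test of the family. Single genes named in this part were likewise chosen after their values were seen. All 10 tested Toll-like receptor genes, which encode sensors of microbial products, rose with BMS-582949 (median log2 fold change 1.58), for example Tlr2 from 31.1 ± 1.70 to 95.3 ± 4.15 CPM and Tlr7 by 1.88. All 5 tested genes of serine and one-carbon synthesis rose (median 1.09), with Psat1 at 1.52. In the Ms4a family 6 of 7 genes rose (median 1.11, and 0.65 without BMS-582949 replicate 2, when 4 were called), led by Ms4a6b at 2.19. For 78 genes with symbols of cytosolic ribosomal proteins the calls depended on scaling and on single libraries, with 33 higher and 7 lower under TMM and 69 and 0 with library size only. They were 38 and 3 without DMSO replicate 1, 17 and 11 without DMSO replicate 2 and 29 and 11 without BMS-582949 replicate 1.

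Subunits of the V-type ATPase, the proton pump that acidifies lysosomes and the resorption pit, fell in 15 of 16 cases (median -1.92). The exception was Atp6v0a1, which rose by 0.56. All 36 tested genes of complex I subunits fell (median -1.04), and of 78 mitochondrial ribosomal protein genes 57 fell and 1 rose (median -0.37). With library size only the last median was 0.01, with 20 higher and 21 lower, so that direction depends on scaling. Metallothionein genes fell in 3 of 3 cases, with Mt3 from 479 ± 31.6 to 37.3 ± 0.984 CPM. The MCM and E2F families rose in 8 of 9 and 6 of 8 cases.

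Of the tests of explanations below, those for the histone genes, for the respiratory chain and for exon overlap were chosen after the results were seen. Summed over 39 tested histone cluster genes, CPM went from 969 ± 17.7 in DMSO to 216 ± 4.03 with BMS-582949, while every cell cycle gene on the list rose. Individually 16 fell, 2 rose and 21 were not called, and 1 rose in each of the 4 fits that left out a library. The sum changed by -2.17 on the log2 scale, and by -1.92 with the GC and length trend removed. Reads shared between near-identical copies would leave genes of mostly unshared sequence in place. The 8 histone genes with under 20% of 50-base words in another gene went from 358 ± 0.988 to 105 ± 2.96 CPM in sum (-1.77, 4 called lower and 0 higher). In DMSO 349 of the 358 CPM came from Hist1h1c (from 232 ± 1.31 to 88.0 ± 3.15 CPM) and Hist2h2be (from 117 ± 0.648 to 10.9 ± 0.951 CPM), and 4 of the other 6, at 2.97 CPM or less, were not called. This argues against shared reads as the cause for those 2 genes. For the 31 genes with more shared sequence, whose sum changed by -2.47, it stays open, because that fall restates the observation. Fewer cells in S phase would lower replication genes too, but the median of 14 such genes, all from a list fixed before the data were examined, was 1.46. A shift in how much histone RNA is polyadenylated may be a candidate explanation and was not tested.

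Respiratory chain genes fell whether encoded in the nucleus or in mitochondria, 38 of 38 with a median of -1.04. The median was -0.97 with the GC and length trend removed and -0.66 with library size only. All 38 remained called lower under both. For the 13 mitochondrially encoded genes the median was -0.92, against -0.62 with the GC and length trend removed and -0.55 with library size only. The values with the trend removed argue against GC and length as the whole cause. Library size only shifted log2 fold changes by a median of 0.38, so its median followed from that shift. It shows that the fall is present under both scalings and does not test scaling as a cause. A lower share of osteoclasts, which are rich in mitochondria, and lower expression per cell both stay open as untested hypotheses. RNA from whole cultures cannot tell them apart, and no macrophage library without RANKL was analysed here.

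Among 8475 genes with at least 10 CPM, 41 differed at least 2-fold between replicates of a group. Of the 37 with coordinates, 48.6% had exons overlapping another model, against 9.29% of other genes (Fisher p = 9.5e-10), and 62.2% shared at least 20% of their 50-base words with another gene, against 3.33% of 300 random genes (Fisher p = 1.5e-18). Exons that overlap on the same strand also share words, so these comparisons are not independent. Reads assigned to one or another of several matching models may be one source, though 13 genes showed neither. Cpeb4, one of the genes without overlap, had 2240 and 111 counts in the BMS-582949 libraries and was still called (adjusted p = 0.020), and no biological explanation was tested.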
